A study of Mus musculus with 15 samples.

How the data were processed

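Total RNA of mouse lungs and kidneys was measured as biotinylated cRNA on Illumina expression arrays, per the labels' protocols. The deposited raw values are probe signal intensities, exported with GenomeStudio 5.0 per the submitters' processing notes, and each comes with a deposited detection p-value. The steps before the export are not given in the sources used here. The deposited matrix values are intensities on a linear scale with the background subtracted, some of them below 0, and their rank correlation with the raw signals was between 0.999992 and 1 per array. Their mean per array was 224 to 231 in healthy lung, 332 to 352 in bleomycin lung, 196 to 226 in UUO-mouse lung, 337 to 369 in healthy kidney and 261 in UUO kidney, and that of the raw signals 363 to 390, 508 to 527, 267 to 424, 402 to 417 and 374 to 449 in the same order. The scaling option is not given in the sources used here. The raw signals were used, and the matrix values served as an alternative, with 47.73% of them under the floor of 16 set before the log2.

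The 15 arrays gave 14 samples in 5 groups: 3 healthy lungs, 3 bleomycin lungs, 3 lungs of UUO mice, 3 healthy kidneys and 2 UUO kidneys. The 2 arrays of UUO-mouse lung replicate 2 (correlation 0.9708, 478 genes apart by over 2-fold, against 363 to 1132 for different mice of that group) were averaged on the log2 scale. The tissue field of 1 healthy kidney sample names the lung, and its title and source were followed. Per the labels' animal numbers, 4 mice gave both a lung and a kidney. As a check of this pairing, the deviations from the group means correlated at -0.122 to 0.185 (median -0.034) between the organs of the same mouse, at -0.565 to 0.169 between samples with the same replicate number and different mice, and at -0.372 to 0.548 for the rest; replicate numbers do not pair the mice.

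Signals were background corrected with the neqc method of limma 3.58.1 in R 4.3.3 (offset 16, negative controls inferred from the detection p, which moves in 936 steps) and quantile normalized over all arrays. Median raw signals were 95.2 to 125.1 and 32.4% to 41.5% of the probes were above background at a detection p under 0.01. Of 45281 probes, 34885 carried 1 gene symbol, 18 several and 10378 none. A probe was kept with a detection p under 0.01 in at least 2 samples (21048 probes, 46.5%; 18022 with 1 gene), and the probe with the highest mean stood for each of 11648 genes. Other kept probes of called genes had the same direction in 77.3% (bleomycin lung), 69.2% (UUO-mouse lung), 79.3% (UUO kidney), 72.4% (bleomycin against UUO-mouse lung) and 83.7% (kidney against lung).

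A linear model with 5 group means was fitted with limma and moderated by eBayes (9 residual and 3.06 prior degrees of freedom), and p-values were adjusted by Benjamini-Hochberg over the genes of a comparison at 0.05. The comparisons were bleomycin and UUO-mouse lung against healthy lung, UUO against healthy kidney, bleomycin against UUO-mouse lung, healthy kidney against healthy lung, and the lung effect of bleomycin minus the kidney effect of UUO. Of 45 gene lists, 43 with at least 5 measured genes were tested with camera (preset correlation between genes 0.01), adjusted over the lists of a comparison. A gene whose probe was at background (detection p of 0.05 or more) in every sample of a group has only a bound there, written as at least N-fold. The bound sets the mean of the brighter group against the mean, in the dim group, of the higher of the probe's own value and the lowest value of any probe above background on that array. In the difference the same limit replaced each group at background that adds to its size, and no bound was given where the probe was at background in a group that lowers it.

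The genes named were chosen by a rule: the 5 largest and 5 smallest changes among genes that passed, whose samples did not overlap and whose probe was above background in every sample of a group; for each list described, up to 2 members that rose and 2 that fell with the smallest adjusted p, or else the 1 with the smallest, said not to pass; always Col1a1, Acta2, Fn1, Pecam1, Cdh5, Tjp1, Ocln and, between lungs, the 4 claudins with the smallest adjusted p and Cldn5; and the 5 smallest p where fewer than 10 passed. Comparisons, lists, this rule and the other settings to try were fixed before the data were examined, except for the settings named below as chosen later. The rule was not followed in full. Acta2 and Fn1 are not given for kidney against lung, and fewer than 4 claudins are named for UUO-mouse lung. The lists of liver, kidney, male-biased and female-biased transcripts were written after the data were seen.

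Alternatives were no background correction, normexp with offset 50, median scaling, the deposited matrix values, normalization within the organ, no filter or a stricter filter, every probe, an intensity trend, array weights, only the groups compared, a 2-fold threshold, the replicate number as a fixed block, the animal as a random block (statmod 1.5.0, correlation 0.079) or, for kidney against lung, as a fixed block, a single array of UUO-mouse lung replicate 2, and leaving out each sample in turn; list tests were repeated with an estimated correlation and with fry. Shared healthy lungs were simulated with 100 pairs of unchanged groups. The scripts were tested on simulated data with 200 of 11648 genes changed by log2 0.5, 1 or 2. They recovered 13.4%, 59.7% and 92.4% for bleomycin lung, 4.5%, 70.1% and 93.9% for UUO-mouse lung, 6%, 55.2% and 89.4% for UUO kidney, 0%, 65.7% and 92.4% for bleomycin against UUO-mouse lung, 3%, 56.7% and 98.5% for kidney against lung and 0%, 13.4% and 71.2% for the difference, and called 9, 6, 5, 12, 7 and 4 unchanged genes. The Benjamini-Hochberg threshold depends on the share of genes changed. These recoveries therefore hold for 200 changed genes and do not give the sensitivity where a large share of genes passed. GC content of the probes was not analysed here.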

Results

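Gene expression was measured on Illumina mouse whole-genome arrays in lungs and kidneys of BALB/c mice. The 5 groups were healthy lung (n = 3), lung made fibrotic by bleomycin given into the trachea (n = 3), lung of mice with kidney fibrosis after unilateral ureteral obstruction (UUO, closure of the ureter of 1 kidney; n = 3), healthy kidney (n = 3) and UUO kidney (n = 2). These 14 samples came from 15 arrays, because 1 UUO-mouse lung was measured on 2 arrays that were averaged. The labels name an animal for each sample, so replicates within a group are separate mice. The p-values rest on a spread between mice pooled over the 5 groups, not on that of the groups compared alone. In all, 4 mice gave both a lung and a kidney, which the main fit did not pair. The series title concerns tight junction claudins, differences between the blood vessels of organs, and metastasis to particular organs, so the comparisons ask how fibrosis changed the lung and the kidney, whether a fibrotic kidney was accompanied by changes in the lung, and how the organs differed before injury. Between 32.4% and 41.5% of the probes on an array were above background, 11648 genes were tested, and the number of arrays limits the precision. Changes are log2 fold changes ± SE from limma, "rose" and "fell" mean an adjusted p under 0.05 over all genes, and gene lists were tested with camera at a preset correlation between genes. With an estimated correlation, the only list calls that held in any comparison were those of the pan-endothelial and alveolar type 1 markers between healthy kidney and healthy lung.

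In the bleomycin lung, matrix, protease, macrophage and cell cycle genes rose and endothelial, lymphocyte, antigen presentation and red cell genes fell relative to the healthy lung (n = 3 each). The largest rises were those of Wfdc17, a small secreted protein of activated macrophages (5.88 ± 0.56, 58.9-fold, adjusted p = 2.12e-05), the matrix glycoprotein Tnc (5.86 ± 0.67, 58.0-fold, adjusted p = 5.7e-05), the metalloproteinase inhibitor Timp1 (5.80 ± 0.78, adjusted p = 0.00014), the cysteine protease inhibitor Stfa1 (5.75 ± 0.93, adjusted p = 0.000477) and the monocyte chemokine Ccl7 (5.33 ± 0.43, adjusted p = 6.91e-06). The largest falls were those of the beta-globin gene Hbb-b2 (-6.23 ± 0.24, adjusted p = 6.72e-08) and of Alas2, which starts heme synthesis in red cell precursors (-5.48 ± 0.45, adjusted p = 8.64e-06), followed by Hbb-bs, Hba-a1 and Hbb-bt at -5.32 ± 0.28, -5.20 ± 0.28 and -4.91 ± 0.28. Col1a1, the main chain of type I collagen, rose by 3.06 ± 0.40 (adjusted p = 0.000119) and Fn1, fibronectin, by 3.05 ± 0.35 (adjusted p = 5.52e-05), while Acta2, the smooth muscle actin of myofibroblasts, had a change of 0.55 ± 0.39 that did not pass (adjusted p = 0.271).

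Of 33 measured fibrillar collagen and matrix genes, 21 rose and 1 fell (22 and 2 adjusted over the list alone). Matrix genes as a list had adjusted p = 6.1e-08, and adjusted p = 0.247 with an estimated correlation. Col5a2 rose by 3.05 ± 0.18, Vcan, versican, was at least 3.67-fold higher, and Fbln1 fell (-1.34 ± 0.31). Among 17 basement membrane genes 11 rose and 1 fell, the same counts as adjusted over the list alone. Basement membrane genes as a list had adjusted p = 0.00477, and adjusted p = 0.26 with an estimated correlation. Among them were Col4a2 at 1.36 ± 0.18, Col4a1 at 1.33 ± 0.18 and Col4a5 at -0.80 ± 0.27. Col4a5 lost its call in 7 of 18 other settings, samples left out included, and was at -0.43 under median scaling and -0.24 with the deposited matrix values, with which Fbln1 did not pass either (-0.76). Matrix proteases and their inhibitors rose in 14 of 22 and fell in 1 (15 and 1 adjusted over the list alone). Matrix proteases and inhibitors as a list had adjusted p = 1.08e-05, and adjusted p = 0.171 with an estimated correlation. Mmp10 was at least 11.5-fold higher and the membrane-bound Mmp14 rose by 2.16 ± 0.20. Macrophage and monocyte markers rose in 18 of 24 and fell in none, as adjusted over the list alone. Macrophage and monocyte markers as a list had adjusted p = 3.22e-07, and adjusted p = 0.263 with an estimated correlation. Among them were the mannose receptor Mrc1 (2.24 ± 0.18) and the lipid receptor Trem2 (3.46 ± 0.28). Chemokines and cytokines rose in 17 of 33 and fell in 4 (18 and 4 adjusted over the list alone). Chemokines and cytokines as a list had adjusted p = 0.0039, and adjusted p = 0.383 with an estimated correlation. Ccl2, which recruits monocytes, was at least 13.4-fold higher, whereas the endothelial chemokine Cx3cl1 (-1.99 ± 0.18) and the T cell chemokine Ccl5 (-2.54 ± 0.28) fell. The list of pre-metastatic niche genes, which holds Ccl2, Vcan and Fn1, rose in 11 of 18 and fell in none, as adjusted over the list alone. Pre-metastatic niche genes as a list had adjusted p = 1.42e-05, and adjusted p = 0.263 with an estimated correlation. Cell cycle genes rose in 19 of 25 and fell in 1 (20 and 1 adjusted over the list alone). Cell cycle genes as a list had adjusted p = 4.14e-07, and adjusted p = 0.263 with an estimated correlation. Among them were the mitotic kinase Cdk1 at 3.23 ± 0.33, Tyms at 2.23 ± 0.23 and the tubulin-binding Stmn1 at -1.33 ± 0.27. The p53 targets rose in 5 of 13 (8 adjusted over the list alone). The p53 list had adjusted p = 0.00872, and adjusted p = 0.321 with an estimated correlation. Among them were Zmat3 (1.34 ± 0.16) and the cell cycle inhibitor Cdkn1a (3.67 ± 0.50).

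Endothelial genes moved the other way. Of 24 pan-endothelial markers 16 fell and none rose, as adjusted over the list alone. Pan-endothelial markers as a list had adjusted p = 5.64e-05, and adjusted p = 0.171 with an estimated correlation. Among them were Eng (-1.39 ± 0.13) and Tie1 (-1.63 ± 0.17). Lung capillary markers fell in 9 of 16 (11 adjusted over the list alone). Lung capillary endothelial markers as a list had adjusted p = 0.00337, and adjusted p = 0.263 with an estimated correlation. Foremost were Sema3c (-2.50 ± 0.23) and the apelin receptor Aplnr (-2.04 ± 0.22). Cdh5, the cadherin of endothelial junctions, fell by 1.02 on the log2 scale (SE 0.19, adjusted p = 0.00114) and Pecam1 was at -0.32 ± 0.19 without passing (adjusted p = 0.186). Among 16 claudins 2 rose and 4 fell (2 and 5 adjusted over the list alone), and the list did not pass (adjusted p = 0.712); its median was -0.21, but 0 under median scaling and 0.23 with the deposited matrix values, its mean 0.10 and its test pointed down. Cldn4, a claudin of epithelial barriers, rose by 4.66 ± 0.44 (adjusted p = 1.99e-05) and the pore-forming Cldn2 by 1.47 ± 0.48 (adjusted p = 0.0274), while Cldn9 (-0.86 ± 0.17, adjusted p = 0.00152), Cldn10 (-0.85 ± 0.29, adjusted p = 0.0296) and the endothelial Cldn5 (-0.53 ± 0.19, adjusted p = 0.0398) fell. Under median scaling and with the deposited matrix values, which raise the median of all genes as given below, Cldn5 was at -0.09 and 0.09, Cldn10 at -0.46 and -0.28 and Ocln at -0.28 and -0.02, none of them past the threshold. With the matrix values Cdh5 (-0.44, adjusted p = 0.0741), Cldn9 (-0.38) and Mpp5 (-0.35) did not pass either. Among 18 other settings the call was lost in 8 for Cldn5, 6 for Cldn10, 5 for Cldn2 (adjusted p = 0.064 to 0.111) and 2 for Ocln. Other tight junction genes rose in 5 of 23 and fell in 5, as adjusted over the list alone (adjusted p = 0.721, with a median of -0.18 that was 0.16 under median scaling and 0.42 with the deposited matrix values, a mean of 0.01 and a test pointing down), with the polarity gene Mpp5 at -0.92 ± 0.18 and Marveld3 at 0.97 ± 0.15. Occludin, Ocln, fell by 0.59 on the log2 scale (SE 0.16, adjusted p = 0.00915), and Tjp1, the scaffold ZO-1, was at -0.28 ± 0.17 (adjusted p = 0.221).

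T cell markers fell in 7 of 10 in the bleomycin lung. T cell markers as a list had adjusted p = 0.00142, and adjusted p = 0.263 with an estimated correlation. Natural killer and cytotoxic markers fell in 7 of 7. Natural killer and cytotoxic markers as a list had adjusted p = 0.000206, and adjusted p = 0.24 with an estimated correlation. B cell and plasma cell markers fell in 7 of 8. B cell and plasma cell markers as a list had adjusted p = 0.000959, and adjusted p = 0.263 with an estimated correlation. Counts adjusted over the list alone were the same, and none of these genes rose. Examples were Cd3e (-2.07 ± 0.20), the perforin gene Prf1 (-1.95 ± 0.15) and the IgM receptor Fcmr (-2.52 ± 0.21). Genes of MHC class II, which present antigen to helper T cells, fell in 8 of 9, also adjusted over the list alone (adjusted p = 0.000206, adjusted p = 0.383 with an estimated correlation), H2-Ab1 by 2.28 on the log2 scale (SE 0.26). Red blood cell genes fell in 6 of 8, also adjusted over the list alone (adjusted p = 5.64e-05, adjusted p = 0.171 with an estimated correlation). Neutrophil markers rose in 5 of 18, also adjusted over the list alone. Neutrophil markers as a list had adjusted p = 0.0117, and adjusted p = 0.655 with an estimated correlation. Among them was Stfa2 at 5.30 ± 0.66. Kidney tubule injury genes, which share Timp1 and Ccl2 with other lists, rose in 12 of 20 and fell in 1 (the same adjusted over the list alone). Kidney tubule injury genes as a list had adjusted p = 0.000298, and adjusted p = 0.395 with an estimated correlation. Hypoxia and glycolysis genes rose in 9 of 17 and fell in 2 (10 and 2 adjusted over the list alone). Hypoxia and glycolysis genes as a list had adjusted p = 0.0154, and adjusted p = 0.59 with an estimated correlation. Acute phase and glucocorticoid response genes rose in 9 of 20 and fell in 1 (the same adjusted over the list alone). Acute phase and glucocorticoid response genes as a list had adjusted p = 0.0281, and adjusted p = 0.655 with an estimated correlation. Among these genes the metal-binding Mt1 rose by 2.34 ± 0.33. The acute phase list had adjusted p = 0.0502 with the animal as a random block and 0.0632 without healthy lung 1, and with fry the acute phase and neutrophil lists had 0.0666 and 0.0527.

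In all, 5019 genes (43.1%) passed between bleomycin and healthy lung, 2484 higher and 2535 lower. The share of higher calls was 49.5%, but 75.1% when each array was scaled to its median and 87.1% with the deposited matrix values. These settings moved the median change of all genes from -0.04 to 0.24 and 0.51. Relative to that median, none of the called lists changed sign under the 5 settings of background and scaling. Subtracting the median removes the shift of all genes, so this check does not test the shift itself. Bleomycin lungs 1 and 2 had the Y-linked Eif2s3y above background (log2 intensity 9.66 and 9.65) and bleomycin lung 3 had Xist at 8.91 and Eif2s3y at background, and 10 of 12 kidney transcripts were above background in bleomycin lung 1, Umod at 9.07. Healthy lung 3, a control here, held liver transcripts (median 12.4, against 4.55 and 4.57 in the other healthy lungs). Without it 4661 genes passed. The labels number the bleomycin mice in another way than all other mice. Mean raw signals were 508 to 527 in bleomycin lungs and 363 to 390 in healthy lungs. A difference between these sets of mice or arrays cannot be told apart from bleomycin in any comparison with these lungs.

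**Figure D1:**
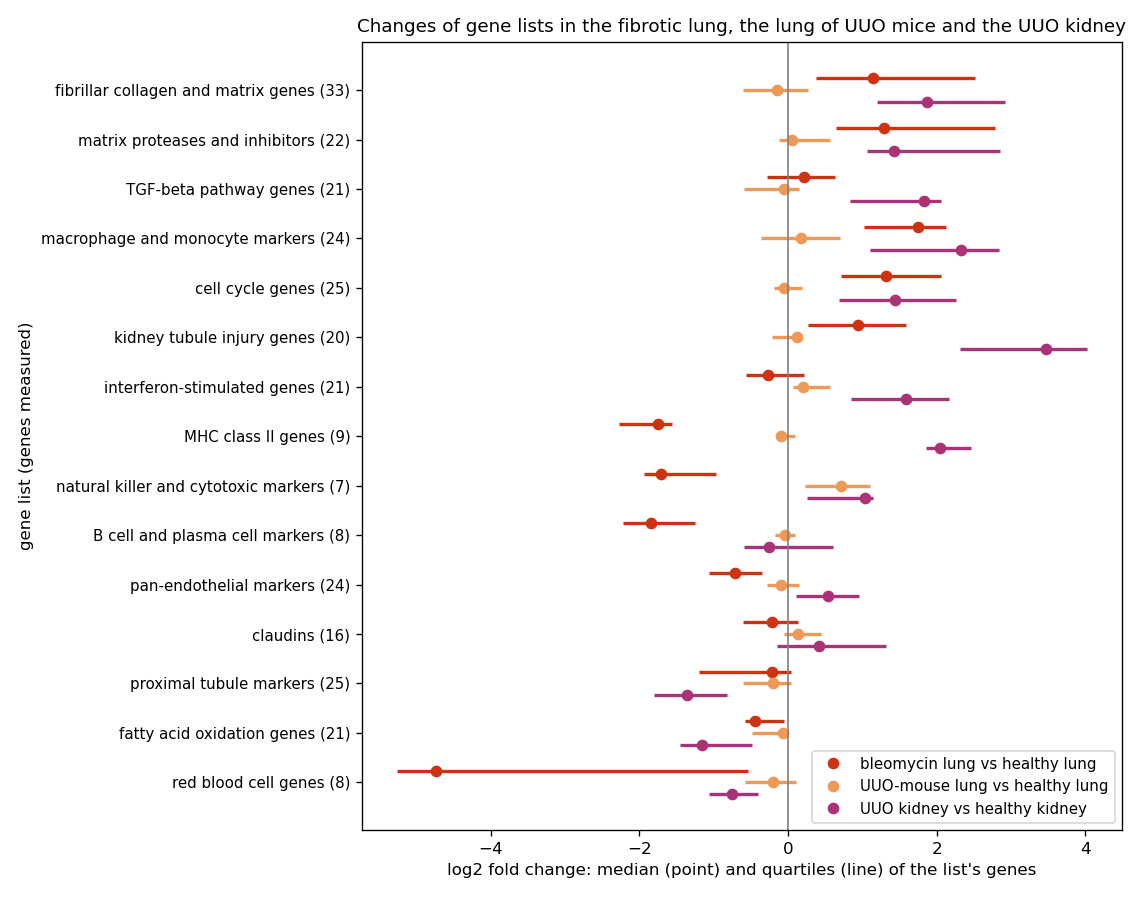
Median (points) and quartiles (lines) of the log2 fold changes of 15 gene lists in the bleomycin lung, the lung of UUO mice and the UUO kidney, each against its healthy organ, with the number of genes measured in parentheses. Pan-endothelial markers had medians of -0.72, -0.10 and 0.54 and MHC class II genes of -1.75, -0.10 and 2.05; none of these signs changed under the scalings tried.

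In the lung of UUO mice, whose own injury was in the kidney, changes were smaller than in the bleomycin lung, and the sex-linked genes differed together with the groups. Xist, the RNA that silences the second X chromosome, was at least 88.5-fold higher than in healthy lung (adjusted p = 0.000956), and the Y-linked Eif2s3y and Kdm5d were at least 21-fold and 2.49-fold lower (adjusted p = 0.0127 and 0.00755; n = 3 each). Every UUO-mouse lung had Xist above background and no Eif2s3y above background, and every healthy lung the reverse. Beyond these, the largest rises were those of the matrix protein Spon2 (2.34 ± 0.56, adjusted p = 0.0235), Grrp1 (1.85 ± 0.29, adjusted p = 0.00453), the collagen cross-linking enzyme Lox (1.83 ± 0.41, adjusted p = 0.0182) and the TNF family ligand Tnfsf14 (1.67 ± 0.49, adjusted p = 0.0471). The largest falls were those of the actin-severing Gsn (-4.18 ± 0.31, adjusted p = 6.65e-05), the inhibitory Smad6 (-2.42 ± 0.18, adjusted p = 6.65e-05), the phospholipid transfer protein Pltp (-2.22 ± 0.26, adjusted p = 0.00114) and the translation factor Eef2 (-2.19 ± 0.20, adjusted p = 0.000287). Among 21 other settings the call was lost in 10 for Tnfsf14 (adjusted p up to 0.14), 5 for Spon2 (up to 0.153), 3 for Lox and 2 for Eif2s3y.

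Fibronectin, Fn1, fell by 1.91 on the log2 scale (SE 0.35, adjusted p = 0.00843), opposite to its rise in the bleomycin lung, and Col1a1 (-0.37 ± 0.40, adjusted p = 0.588) and Acta2 (-0.14 ± 0.39, adjusted p = 0.854) did not pass. Of 33 fibrillar collagen and matrix genes 1 rose and 5 fell (2 and 6 adjusted over the list alone; adjusted p = 0.113), among them the procollagen processing factor Pcolce (-0.83 ± 0.13) and Col6a2 (-1.14 ± 0.20). The pre-metastatic niche list had 1 rise, Lox, and 1 fall, Fn1, among 18 genes, also adjusted over the list alone (adjusted p = 0.657). Cdh5 (-0.15 ± 0.19, adjusted p = 0.654), Pecam1 (-0.29 ± 0.19, adjusted p = 0.334), Tjp1 (0.30 ± 0.17, adjusted p = 0.292) and Ocln (-0.06 ± 0.16, adjusted p = 0.852) did not pass. Pan-endothelial markers fell in 2 of 24, also adjusted over the list alone (adjusted p = 0.338): Eng (-0.62 ± 0.13) and Tie1 (-0.66 ± 0.17). Lung capillary markers had 1 rise, the fatty acid transporter Cd36 (at least 1.84-fold higher), and 1 fall, the transcription factor Foxf1 (-0.80 ± 0.19), among 16 (1 and 2 adjusted over the list alone; adjusted p = 0.282). Of 16 claudins 1 rose, Cldn10 (1.03 ± 0.29, adjusted p = 0.0412), and none adjusted over the list alone (adjusted p = 0.627), while Cldn5 (0.43 ± 0.19, adjusted p = 0.158) and Cldn4 (0.85 ± 0.44, adjusted p = 0.227) did not pass. The claudin list's median was 0.14 but -0.07 under median scaling. Without healthy lung 3 and UUO-mouse lung 1, which held liver transcripts, Fn1 was at -1.66 (adjusted p = 0.0545), Eng at -0.46 (0.159), Tie1 at -0.49 (0.22), Foxf1 at -0.58 (0.176) and Cldn10 at 0.56 (0.298). Of 21 other settings 11 lost the call of Cldn10, 8 that of Foxf1, 6 that of Tie1, 5 that of Eng and 1 that of Fn1.

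Natural killer and cytotoxic markers rose in 4 of 7, also adjusted over the list alone. Natural killer and cytotoxic markers as a list had adjusted p = 0.0235, and adjusted p = 0.913 with an estimated correlation. Among them were the receptor genes Klrd1 at 1.40 ± 0.21 and Klre1 at 1.20 ± 0.19. Alveolar type 1 markers fell as a list, with 1 of 18 past the threshold, Clic5 (-0.83 ± 0.23), and 6 adjusted over the list alone. Alveolar type 1 markers as a list had adjusted p = 0.0235, and adjusted p = 0.913 with an estimated correlation. Heart muscle genes fell as a list, with 1 of 12 past the threshold, Myh7 (at least 1.06-fold lower), also adjusted over the list alone. Heart muscle genes as a list had adjusted p = 0.0442, and adjusted p = 0.913 with an estimated correlation. Skeletal muscle genes also fell as a list, with 0 of 8 past the threshold over all genes or adjusted over the list alone (adjusted p = 0.0365, adjusted p = 0.913 with an estimated correlation). With the animal as a random block, the adjusted p of the alveolar type 1 list was 0.0563 and that of both muscle lists 0.0959. Without healthy lung 2 the heart and skeletal muscle lists had adjusted p = 0.378 and 0.293, without UUO-mouse lung 2 they had 0.332 and 0.114, and the heart list had 0.139 without healthy lung 1. The alveolar type 1 list had 0.059 without healthy lung 3 and 0.0672 without UUO-mouse lung 2. Clic5 and Myh7 lost their calls in 7 of 21 and 12 of 20 other settings. The mean levels of the muscle genes varied among the healthy lungs, from 5.63 to 10.82 and from 5.49 to 10.95 on the log2 scale. Liver transcripts, chosen as a list after the data were seen, had a median log2 intensity of 12.4 in healthy lung 3 and 10.3 in UUO-mouse lung 1, against 4.55 to 5.11 in the other lungs of these groups.

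A total of 1265 genes (10.9%) passed, 677 higher and 588 lower, and 3308 had an unadjusted p under 0.05. The share of higher calls was 53.5%, but 3.3% under median scaling and 15.8% with the deposited matrix values, which moved the median change of all genes from 0.05 to -0.26 and -0.11. The count was 345 (122 higher, 223 lower, 241 of them among the 1265) without the 2 lungs with liver transcripts, and 303 without UUO-mouse lung 3, 483 without healthy lung 1, 523 without healthy lung 3, 670 without UUO-mouse lung 1 and 838 without healthy lung 2.

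**Figure D2:**
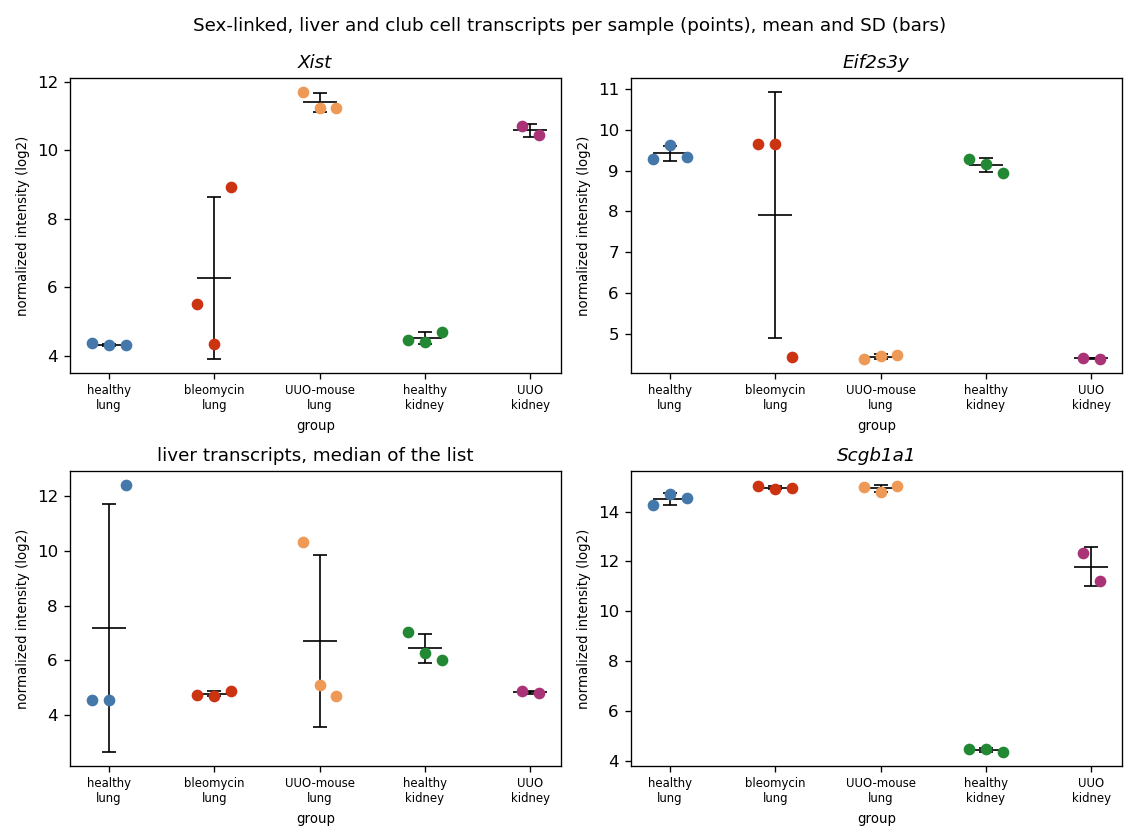
Normalized log2 intensity per sample of Xist, Eif2s3y, the liver transcripts (median of 15 genes) and Scgb1a1 in the 5 groups; points are samples, horizontal bars means and error bars SD. Xist was between 10.4 and 11.7 in the 5 samples of UUO mice and at most 4.71 in the 6 healthy samples, the liver transcripts were at 12.4 and 10.3 in healthy lung 3 and UUO-mouse lung 1, and Scgb1a1 was at 12.3 and 11.2 in the UUO kidneys.

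In the UUO kidney (n = 2) genes of matrix, tubule injury, interferon response and macrophages rose and genes of the proximal tubule and of fatty acid oxidation fell relative to the healthy kidney (n = 3). Lcn2, a secreted marker of tubule injury, rose by 7.15 ± 0.81 (141-fold, adjusted p = 3.34e-05), Timp1 was at least 76.5-fold higher (adjusted p = 6.37e-05) and the chemokine Ccl9 rose by 5.61 ± 0.49 (adjusted p = 5.63e-06). Scgb1a1, the main secreted protein of airway club cells, was at least 93.1-fold higher (adjusted p = 6.61e-09). The largest falls were those of Acsm3, a medium-chain acyl-CoA synthetase (-7.45 ± 0.65, adjusted p = 5.58e-06), the major urinary protein gene Mup2 (-6.64 ± 2.50, adjusted p = 0.0487), the organic anion transporter genes Slc22a30 (-6.49 ± 0.59, adjusted p = 7.55e-06) and Slc22a28 (-6.15 ± 0.55, adjusted p = 6.74e-06), and the cytochrome P450 gene Cyp2d12 (-5.20 ± 0.21, adjusted p = 2.27e-08). Mup2 lost its call in 11 of 17 other settings, among them each of the 5 with a sample left out, with adjusted p up to 0.174. Liver transcripts, a list written after the data were seen, had medians of 7.05, 6.27 and 6.01 in the healthy kidneys and 4.87 and 4.80 in the UUO kidneys. As in the lungs of UUO mice, Xist was at least 40.3-fold higher (adjusted p = 0.000212) and Eif2s3y and Kdm5d at least 17.0-fold and 2.01-fold lower (adjusted p = 0.00516 and 0.00919). Kdm5d lost its call in 1 of 17 other settings, with a sample left out.

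Col1a1 rose by 4.14 ± 0.44 (adjusted p = 2.24e-05), Acta2 by 2.18 ± 0.43 (adjusted p = 0.00164) and Fn1 by 3.03 ± 0.39 (adjusted p = 7.54e-05). Fibrillar collagen and matrix genes rose in 27 of 33 and fell in none, also adjusted over the list alone. Matrix genes as a list had adjusted p = 3.08e-10, and adjusted p = 0.231 with an estimated correlation. Among them were Sparc at 2.40 ± 0.17 and the cross-linking enzyme Loxl1 at 2.77 ± 0.20. Basement membrane genes rose in 12 of 17 and fell in 3 (13 and 3 adjusted over the list alone). Basement membrane genes as a list had adjusted p = 0.0024, and adjusted p = 0.231 with an estimated correlation. Col4a1 rose by 2.92 ± 0.20 and Col4a2 by 2.39 ± 0.20, whereas Col4a3 (-1.53 ± 0.28) and Col4a4 (-1.03 ± 0.15), chains of the glomerular basement membrane, fell. Matrix proteases and inhibitors rose in 16 of 22, also adjusted over the list alone (adjusted p = 3.35e-05, adjusted p = 0.231 with an estimated correlation), Mmp14 by 3.78 ± 0.22 and Mmp2 by 3.15 ± 0.20. TGF-beta pathway genes rose in 18 of 21 and fell in 1 (19 and 1 adjusted over the list alone). TGF-beta pathway genes as a list had adjusted p = 3.35e-06, and adjusted p = 0.231 with an estimated correlation. Among them were the latent TGF-beta binding protein Ltbp3 at 2.06 ± 0.22 and Smad6 at -0.64 ± 0.21. Myofibroblast and pericyte markers rose in 12 of 18 and fell in 1 (12 and 2 adjusted over the list alone; adjusted p = 0.00551, adjusted p = 0.38 with an estimated correlation), Thy1 by 4.35 ± 0.45, while the pericyte gene Rgs5 fell (-1.05 ± 0.32). Smad6 lost its call in 10 and Rgs5 in 4 of 17 other settings.

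Kidney tubule injury genes rose in 18 of 20 (19 adjusted over the list alone). Kidney tubule injury genes as a list had adjusted p = 3.08e-10, and adjusted p = 0.231 with an estimated correlation. Among them were the adhesion molecule Vcam1 at 3.996 ± 0.173 and Sox4 at 3.57 ± 0.25. Proximal tubule markers fell in 14 of 25 and rose in 1, also adjusted over the list alone. Proximal tubule markers as a list had adjusted p = 1.24e-05, and adjusted p = 0.38 with an estimated correlation. The organic anion transporter Slc22a6 fell by 3.21 on the log2 scale (SE 0.23), the amino acid transporter Slc7a13 was at least 5.66-fold lower, and the sulfate transporter Slc13a1 rose by 2.10 ± 0.22. A list of 10 male-biased kidney genes, chosen after the data were seen, had a median change of -3.87 with 9 falls, 23 other proximal tubule markers a median of -1.19, and 4 female-biased kidney genes a median of 3.14 with 3 rises. Slc7a13 was on the male-biased list. Fatty acid oxidation genes fell in 14 of 21, also adjusted over the list alone. Fatty acid oxidation genes as a list had adjusted p = 8.33e-07, and adjusted p = 0.315 with an estimated correlation. Among them were Ppara, the transcription factor that drives the pathway (-2.38 ± 0.27), and Acadl (-2.01 ± 0.25).

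Macrophage, chemokine, interferon, MHC class II and complement lists rose in the UUO kidney. Macrophage and monocyte markers rose in 17 of 24 and fell in 2 (18 and 2 adjusted over the list alone). Macrophage and monocyte markers as a list had adjusted p = 3.35e-06, and adjusted p = 0.38 with an estimated correlation. Among them were Mrc1 at 3.35 ± 0.20 and the microglia and macrophage gene Aif1 at 2.40 ± 0.19. Chemokines and cytokines rose in 20 of 33 and fell in 2 (22 and 2 adjusted over the list alone; adjusted p = 2.42e-05, adjusted p = 0.273 with an estimated correlation), Ccl5 by 4.42 ± 0.31. Interferon-stimulated genes rose in 16 of 21 (17 adjusted over the list alone). Interferon-stimulated genes as a list had adjusted p = 7.41e-06, and adjusted p = 0.269 with an estimated correlation. The regulator Irf7 was at least 4.03-fold higher. MHC class II genes rose in 7 of 9, also adjusted over the list alone (adjusted p = 0.000498, adjusted p = 0.39 with an estimated correlation), H2-Ab1 by 2.46 ± 0.29. Complement genes rose in 5 of 10 and fell in 1 (6 and 1 adjusted over the list alone). Complement genes as a list had adjusted p = 0.0404, and adjusted p = 0.453 with an estimated correlation. Among them were properdin, Cfp, at 3.27 ± 0.26 and the complement inhibitor Cd55 at -2.16 ± 0.31. Pre-metastatic niche genes rose in 11 of 18 and fell in 1, also adjusted over the list alone. Pre-metastatic niche genes as a list had adjusted p = 0.00185, and adjusted p = 0.38 with an estimated correlation. Cell cycle genes rose in 18 of 25, also adjusted over the list alone. Cell cycle genes as a list had adjusted p = 4.57e-06, and adjusted p = 0.38 with an estimated correlation. Among them were the cytokinesis gene Prc1 at 3.02 ± 0.34 and the replication helicase gene Mcm6 at 2.50 ± 0.29. Acute phase and glucocorticoid response genes rose in 8 of 20, also adjusted over the list alone. Acute phase and glucocorticoid response genes as a list had adjusted p = 0.0185, and adjusted p = 0.528 with an estimated correlation. Among them was the cytokine signalling inhibitor Socs3 at 5.30 ± 0.50. Immediate early genes rose in 8 of 14, also adjusted over the list alone. Immediate early genes as a list had adjusted p = 0.022, and adjusted p = 0.528 with an estimated correlation. Among them was Atf3 at 4.75 ± 0.53. Without UUO kidney 2 the acute phase list had adjusted p = 0.153, the immediate early list 0.114 and the complement list 0.0522. Mean levels of the acute phase genes were 8.33 and 10.1 in UUO kidneys 1 and 2 and 7.35 to 7.55 in the healthy kidneys. Without healthy kidney 2 the immediate early list had 0.0815, and without UUO kidney 1 the complement list had 0.0696.

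Of the endothelial lists only the pan-endothelial markers passed in the UUO kidney. Pan-endothelial markers rose in 11 of 24 and fell in 1, also adjusted over the list alone (adjusted p = 0.0428, adjusted p = 0.38 with an estimated correlation), Eng by 0.96 ± 0.15 and Egfl7 by 0.98 ± 0.16, while the VEGF receptor Kdr was at least 1.57-fold lower. Cdh5 rose by 1.18 ± 0.21 (adjusted p = 0.000851), Pecam1 by 0.72 ± 0.21 (adjusted p = 0.0155) and Tjp1 by 0.97 ± 0.19 (adjusted p = 0.00163), and Ocln was at 0.04 ± 0.18 (adjusted p = 0.873). Claudins rose in 6 of 16 and fell in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.285), with Cldn3 at 2.63 ± 0.29, Cldn6 at 2.29 ± 0.27 and Cldn9 at -0.53 ± 0.19. Other tight junction genes rose in 7 of 23 and fell in 3, also adjusted over the list alone (adjusted p = 0.697), with the polarity gene Mpp5 at -2.00 ± 0.20. With the animal as a random block, the adjusted p of the pan-endothelial list was 0.0966 and that of Mup2 0.0514. The pan-endothelial list had 0.0543, 0.0815 and 0.0655 without healthy kidney 1, healthy kidney 2 and UUO kidney 2. Of 17 other settings 11 lost the call of Cldn9, which was at -0.24 under median scaling, and 3 that of Pecam1, at 0.56 (adjusted p = 0.128) without UUO kidney 2. Kdr lost its call in 3 of 16.

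In total 5003 genes (43.0%) passed between UUO and healthy kidney, 3032 higher and 1971 lower. With the spread taken from these kidneys alone instead of all 5 groups, 4079 passed. The 2 UUO kidneys differed by over 2-fold in 1177 genes (correlation 0.9565), against 225 to 271 genes between healthy kidneys; mean levels were 9.77 and 11.12 for tubule injury genes, 10.34 and 9.21 for proximal tubule markers and 5.19 and 7.75 for neutrophil markers. The share of higher calls was 60.6%, but 78.0% under median scaling and 34.6% with the deposited matrix values, which moved the median change of all genes from 0.12 to 0.33 and -0.21.

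**Figure D3:**
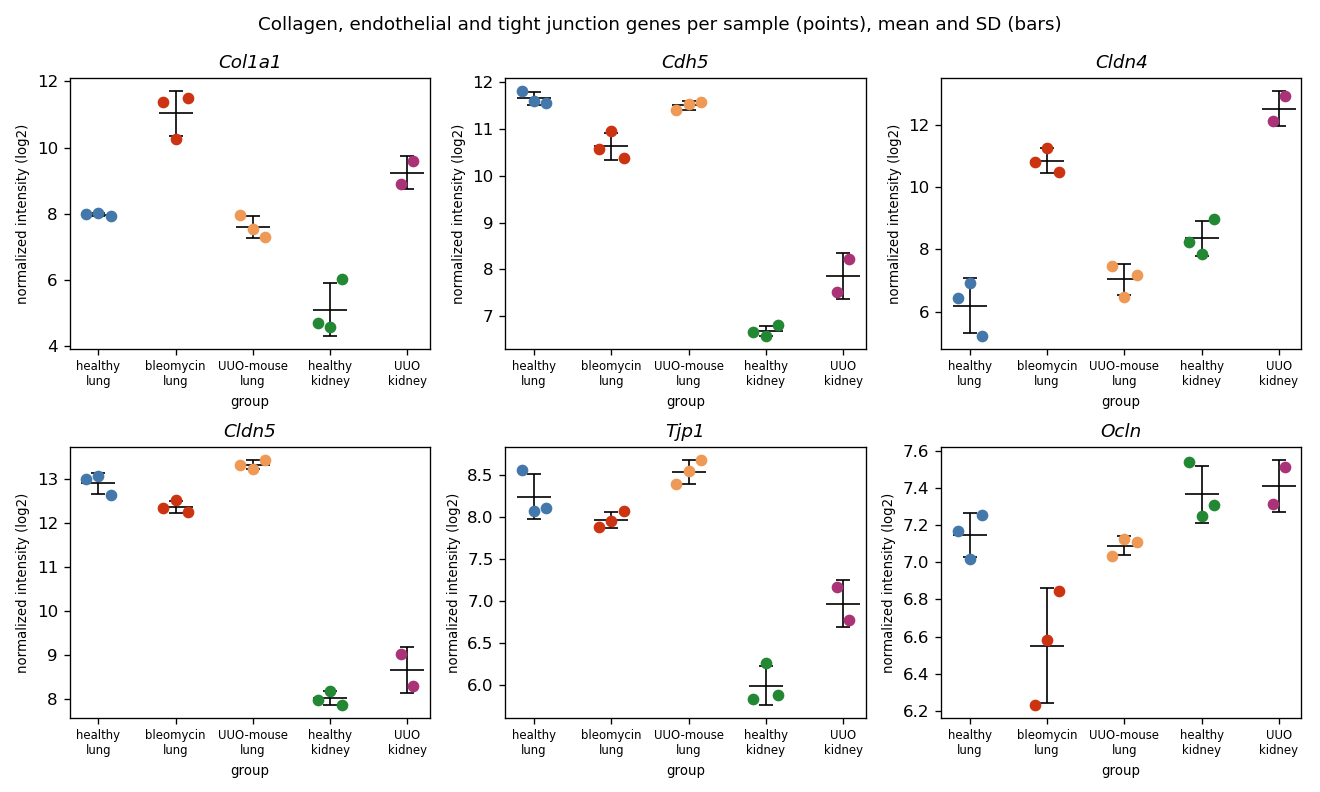
Normalized log2 intensity per sample of Col1a1, Cdh5, Cldn4, Cldn5, Tjp1 and Ocln in the 5 groups; points are samples, horizontal bars means and error bars SD. Col1a1 was between 10.3 and 11.5 in the bleomycin lungs and between 7.93 and 8.03 in the healthy lungs, and Cdh5 was lower in the 3 bleomycin lungs than in the 3 healthy lungs and higher in the 2 UUO kidneys than in the 3 healthy kidneys.

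The test of the difference between the effect of bleomycin on the lung and of UUO on the kidney asked whether fibrosis acted alike on both organs. Endothelial and antigen presentation genes went apart: Cdh5 differed by -2.21 ± 0.29 (lung minus kidney, adjusted p = 9.94e-05), Pecam1 by -1.04 ± 0.28 (adjusted p = 0.0101), and the MHC class II gene H2-Ab1 by -4.74 ± 0.39 (adjusted p = 7.54e-06). The largest differences in favour of the kidney were those of the Fc receptor-like gene Fcrls (at least 88.8-fold), Ccl5 (-6.96 ± 0.42), Scgb1a1 (at least 68.3-fold), Serpina10 (-6.58 ± 1.65) and Thy1 (-6.29 ± 0.60), and in favour of the lung those of Acsm3 (6.70 ± 0.87), Ugt1a7c (5.93 ± 0.36), the metal transporter Slc39a8 (5.78 ± 0.63), the sterol enzyme Nsdhl (5.69 ± 0.39) and Slc22a30, whose probe was at background in the bleomycin lungs and whose difference thus rests on its kidney fall. Fn1 (0.02 ± 0.52, adjusted p = 0.981) and Col1a1 (-1.08 ± 0.60, adjusted p = 0.16) did not pass, whereas Acta2 (-1.63 ± 0.58, adjusted p = 0.0383), Tjp1 (-1.25 ± 0.26, adjusted p = 0.00221) and Ocln (-0.64 ± 0.24, adjusted p = 0.0432, but 0.13 with the deposited matrix values) did. Among 16 claudins 5 changes were lower in the lung than in the kidney, also adjusted over the list alone (list adjusted p = 0.374), with Cldn3 at -2.65 ± 0.38, Cldn1 at -3.01 ± 0.45 and Cldn5 at -1.17 ± 0.28. With the deposited matrix values Pecam1 (-0.27), Acta2 (-0.74), Tjp1 (-0.40) and Cldn5 (-0.35) did not pass. Of 22 other settings 13 lost the call of Ocln and 9 that of Acta2, which had adjusted p = 0.13 and 0.135 without UUO kidney 2.

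Pan-endothelial, lung capillary, interferon, MHC class II and lymphocyte lists had the lower change in the lung. Pan-endothelial markers were lower in 18 of 24 (18 lower and 1 higher adjusted over the list alone; adjusted p = 0.000394, adjusted p = 0.494 with an estimated correlation), among them Eng (-2.35 ± 0.20) and Egfl7 (-2.08 ± 0.21). Lung capillary markers were lower in 11 of 16 and higher in 1 (11 and 2 adjusted over the list alone; adjusted p = 0.0121, adjusted p = 0.494 with an estimated correlation), with Aplnr at -4.05 ± 0.33. Of 21 TGF-beta pathway genes 14 were lower (16 adjusted over the list alone; adjusted p = 0.00126, adjusted p = 0.494 with an estimated correlation), with the latent TGF-beta binding protein Ltbp4 at -3.26 ± 0.31. Interferon-stimulated genes were lower in 18 of 21, also adjusted over the list alone (adjusted p = 0.00013, adjusted p = 0.494 with an estimated correlation), with the RNA sensor gene Dhx58 at least 3.21-fold lower. Several lists had the same counts adjusted over the list alone. MHC class II genes were lower in 8 of 9 (adjusted p = 0.00013, adjusted p = 0.494 with an estimated correlation), H2-Eb1 at -5.05 ± 0.48. Natural killer and cytotoxic markers were lower in 6 of 7 (adjusted p = 0.00198, adjusted p = 0.494 with an estimated correlation), Prf1 at -2.48 ± 0.23. T cell markers were lower in 7 of 10 (adjusted p = 0.0155, adjusted p = 0.519 with an estimated correlation), Cd3e at least 5.03-fold lower. B cell and plasma cell markers were lower in 4 of 8 (adjusted p = 0.0434, adjusted p = 0.712 with an estimated correlation), Fcmr at least 9.53-fold lower. Immediate early genes were lower in 8 of 14 (adjusted p = 0.0233, adjusted p = 0.729 with an estimated correlation), Jun at -2.96 ± 0.27. Red blood cell genes were lower in 6 of 8 and higher in 1 (adjusted p = 0.0261, adjusted p = 0.494 with an estimated correlation), Hbb-b2 at -5.61 ± 0.36. Adherens junction genes were lower in 9 of 14 (adjusted p = 0.0275, adjusted p = 0.592 with an estimated correlation), and their median of -0.88 was 0.19 with the deposited matrix values. Proximal tubule markers had the higher change in the lung in 9 of 25 and the lower in 1 (adjusted p = 0.00727, adjusted p = 0.712 with an estimated correlation). No value is given for Slc22a6, whose probe was at background in every lung. Fatty acid oxidation genes had the higher change in the lung in 8 of 21 (adjusted p = 0.0131, adjusted p = 0.712 with an estimated correlation), Acadl at 2.24 ± 0.33. Both lists fell in the UUO kidney and were lower in healthy lung than in healthy kidney. A higher difference of their genes thus need not mean a rise in the lung. Counts differed for 2 further lists. Kidney tubule injury genes were lower in 14 of 20 and higher in 1 (15 and 1 adjusted over the list alone; adjusted p = 0.00196, adjusted p = 0.686 with an estimated correlation), Sox4 at -4.39 ± 0.33. Alveolar type 2 markers were lower in 10 of 19 and higher in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.0149, adjusted p = 0.494 with an estimated correlation), and their median of -0.87 was 0.10 with the deposited matrix values. Without UUO kidney 2 the adherens junction list had adjusted p = 0.0682, the proximal tubule list 0.0844, the fatty acid oxidation list 0.0935 and the immediate early list 0.103. The B cell list had 0.0506 to 0.06 without each of 6 samples in turn, 0.149 without background correction and 0.0548 with the replicate block.

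The difference passed for 5238 genes, 2085 higher and 3153 lower. The share of higher differences was 39.8% and became 42.5% under median scaling and 84.2% with the deposited matrix values, which moved the median difference of all genes from -0.17 to -0.11 and 0.73. Of the genes called in both organs, 1177 had opposite directions, 475 higher in the lung and lower in the kidney and 702 the reverse. All 1177 passed the test of the difference. Opposite changes add up in that difference, so their passing is close to given and is no separate evidence. Another 251 genes had the same direction in both organs and a difference that passed. Over all 11648 genes, 1153 were called in the same direction in both organs, against 1075.5 for independent lists, and 1177 in opposite directions, against 1080.2; the correlation of the changes across genes was 0.169 (Spearman 0.065), and genes are not independent replicates. Between the lung of UUO mice and the UUO kidney, which share 1 mouse, have healthy organs of the same mice and show the same sex-linked pattern, 506 genes were called in the same direction, against 275.7, and 143 in opposite directions, against 267.6 (correlation across genes 0.243, Spearman 0.229). Between the bleomycin and the UUO-mouse lung, compared with the same healthy lungs, 348 were called in the same direction, against 272.3, and 296 in opposite directions, against 272.7. Their correlation across genes was 0.162, below the mean of 0.497 that 100 simulated pairs of unchanged groups gave with these shared controls. The covariance was 0.0674 against 0.0415 simulated, a difference of 0.0259. Part of these values may come from the shared healthy lungs, which are too few to split. The simulation cannot tell how much, since its groups had no effects and a normal spread pooled over the 5 groups.

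The bleomycin lung was also compared with the lung of UUO mice, the pair of lungs that both came from mice with a fibrotic organ (n = 3 each). Rnase2a was at least 58.2-fold higher in the bleomycin lung (adjusted p = 3.9e-06), and Tnc (5.39 ± 0.67), the arginine-degrading enzyme Arg1 (5.27 ± 1.64), the airway secretory gene Bpifa1 (5.08 ± 1.63) and Wfdc17 (4.997 ± 0.562) were higher with adjusted p of at most 0.0206. Hbb-b2 (-5.58 ± 0.24), Hbb-bs (-5.53 ± 0.28), Hba-a1 (-5.15 ± 0.28), Xist (-5.13 ± 0.80) and Hbb-bt (-5.10 ± 0.28) were lower. The sex-linked pattern was unbalanced in this pair too. Bleomycin lungs 1 and 2 had Eif2s3y above background (9.66 and 9.65), while every UUO-mouse lung had it at background. Fn1 rose by 4.95 ± 0.35 (adjusted p = 1.78e-06) and Col1a1 by 3.43 ± 0.40 (adjusted p = 3.71e-05), while Acta2 (0.69 ± 0.39, adjusted p = 0.156) and Pecam1 (-0.03 ± 0.19, adjusted p = 0.912) did not pass. Pecam1 passed as a rise of 0.66 (adjusted p = 0.0399) under median scaling and 0.63 (adjusted p = 0.0128) with the deposited matrix values. Cdh5 fell by 0.87 on the log2 scale (adjusted p = 0.0024), but was at -0.15 (adjusted p = 0.604) under median scaling and -0.19 (adjusted p = 0.434) with the deposited matrix values. Tjp1 (-0.57 ± 0.17, adjusted p = 0.0157) and Ocln (-0.54 ± 0.16, adjusted p = 0.013) fell with quantile normalization but had changes of 0.17 and 0.19 under median scaling and 0.20 and 0.34 with the deposited matrix values. Cldn4 (3.81 ± 0.44, adjusted p = 3.48e-05) and Cldn2 (2.05 ± 0.48, adjusted p = 0.00394) rose and Cldn10 (-1.89 ± 0.29, adjusted p = 0.000222) and Cldn5 (-0.96 ± 0.19, adjusted p = 0.00126) fell, Cldn5 being at -0.26 and -0.30 without passing under the same 2 scalings. Among 20 other settings the call was lost in 4 for Bpifa1, Tjp1 and Ocln and in 2 for Arg1, Cdh5 and Cldn5.

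Of 43 lists 10 passed upwards and 7 downwards in this pair. Matrix genes rose in 23 of 33 and fell in 2 (25 and 2 adjusted over the list alone). Matrix genes as a list had adjusted p = 1.96e-09, and adjusted p = 0.195 with an estimated correlation. Macrophage markers rose in 19 of 24 and fell in 2 (20 and 3 adjusted over the list alone). Macrophage and monocyte markers as a list had adjusted p = 8.7e-06, and adjusted p = 0.417 with an estimated correlation. Among them was the complement gene C1qc at 3.31 ± 0.28. Natural killer markers fell in 7 of 7, also adjusted over the list alone. Natural killer and cytotoxic markers as a list had adjusted p = 5.17e-05, and adjusted p = 0.195 with an estimated correlation. Klrd1 fell by 3.33 on the log2 scale. T cell markers fell in 9 of 10, also adjusted over the list alone (adjusted p = 0.000252, adjusted p = 0.195 with an estimated correlation). Pan-endothelial markers fell in 16 of 24 and rose in 1 (17 and 1 adjusted over the list alone). Pan-endothelial markers as a list had adjusted p = 0.00128, and adjusted p = 0.195 with an estimated correlation. Lung capillary markers fell in 7 of 16 and rose in 1, also adjusted over the list alone. Lung capillary endothelial markers as a list had adjusted p = 0.0497, and adjusted p = 0.464 with an estimated correlation. Without each of bleomycin lungs 1 and 2 and UUO-mouse lungs 2 and 3 this list had adjusted p = 0.0605, 0.0623, 0.108 and 0.051. Its median of -0.66 was 0.07 under median scaling and 0.06 with the deposited matrix values. In this pair 5828 genes passed, 2593 higher and 3235 lower; the share of higher calls was 44.5%, but 86.1% under median scaling and 89.0% with the deposited matrix values, which moved the median change of all genes from -0.09 to 0.49 and 0.63.

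Healthy kidney and healthy lung of the same 3 mice differed in the genes of their own epithelia, and the lung had the higher levels of endothelial genes. Umod, the main protein of normal urine, was at least 715-fold higher in the kidney (adjusted p = 4.12e-07), the phosphate transporter Slc34a1 rose by 9.77 ± 0.73, Dnase1 and the kallikrein gene Klk1b27 were at least 585-fold and 534-fold higher, and the androgen-regulated Kap rose by 9.29 ± 0.30. The surfactant genes Sftpd and Sftpc were at least 646-fold and 414-fold lower, Scgb1a1 at least 615-fold lower, and Cyp2f2, a cytochrome P450 of club cells, and Chil1 fell by 8.48 and 8.38 on the log2 scale. Pan-endothelial markers were lower in the kidney in 20 of 24 and higher in 1, also adjusted over the list alone (adjusted p = 4.45e-08, adjusted p = 0.0498 with an estimated correlation), Cdh5 by -4.97 ± 0.19 (adjusted p = 6.6e-10) and Pecam1 by -3.46 ± 0.19 (adjusted p = 1.3e-08). Claudins were higher in 8 of 16 and lower in 4, also adjusted over the list alone (adjusted p = 0.141): the kidney had Cldn16 at least 20.3-fold and Cldn19 at least 7.48-fold higher, both claudins of the thick ascending limb, and the lung had the higher Cldn18 (-6.91 ± 0.17), a claudin of alveolar epithelium, and Cldn5 (-4.89 ± 0.19). Tjp1 was lower in the kidney (-2.25 ± 0.17, adjusted p = 2.53e-07), and Ocln was at 0.22 ± 0.16 (adjusted p = 0.235).

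Alveolar type 1 markers were lower in the kidney in 18 of 18, also adjusted over the list alone. Alveolar type 1 markers as a list had adjusted p = 4.06e-10, and adjusted p = 0.0498 with an estimated correlation. Alveolar type 2 markers were lower in 15 of 19 and higher in 1, also adjusted over the list alone. Alveolar type 2 markers as a list had adjusted p = 8.49e-07, and adjusted p = 0.0518 with an estimated correlation. Proximal tubule markers were higher in 22 of 25 and lower in 1 (23 and 1 adjusted over the list alone). Proximal tubule markers as a list had adjusted p = 9.48e-10, and adjusted p = 0.313 with an estimated correlation. Fatty acid oxidation genes were higher in 19 of 21, also adjusted over the list alone (adjusted p = 8.49e-07, adjusted p = 0.313 with an estimated correlation), Ehhadh by 4.46 ± 0.23. Matrix genes were lower in 24 of 33, also adjusted over the list alone (adjusted p = 2.87e-05, adjusted p = 0.323 with an estimated correlation), Col1a1 by -2.87 ± 0.40 (adjusted p = 4.01e-05). Interferon-stimulated genes were lower in 17 of 21, also adjusted over the list alone. Interferon-stimulated genes as a list had adjusted p = 0.000514, and adjusted p = 0.323 with an estimated correlation. In all 7762 genes (66.6%) passed, 3469 higher and 4293 lower in the kidney; the share of higher calls was 44.7%, but 35.7% under median scaling and 64.7% with the deposited matrix values, which moved the median change of all genes from -0.14 to -0.30 and 0.32. Heart muscle genes were lower in the kidney in 10 of 12, also adjusted over the list alone (adjusted p = 0.0329, adjusted p = 0.525 with an estimated correlation). The adjusted p of this list was 0.224 with the animal as a random block and 0.0802 without healthy lung 2. The liver transcripts of healthy lung 3 were part of this comparison.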

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

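The comparison of the lung and kidney effects was planned, while the tests of the sex of the mice, of liver transcripts and of Scgb1a1 weighed below were chosen only after the results were seen. The test of the difference between the effect of bleomycin on the lung and of UUO on the kidney passed for 5238 genes and 15 gene lists. Of the genes that the rule always names, Acta2 (-1.63), Pecam1 (-1.04), Cdh5 (-2.21), Tjp1 (-1.25) and Ocln (-0.64) passed. Cldn5 (-1.17) passed too, while Col1a1 (-1.08) and Fn1 (0.02) did not. These values are log2 changes in the lung minus those in the kidney. Over all 11648 genes, 45% passed. Of 22 other settings 13 lost the call of Ocln and 9 that of Acta2. The organs were injured by different means, and the sex-linked genes differed between the UUO and healthy kidneys, so the difference is one of organ, injury and mice together.

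The first pattern is the sex-linked genes: 5 of 5 samples of UUO mice had Xist above background and Eif2s3y not, and 6 of 6 healthy samples the reverse, which fits female UUO mice and male healthy mice. Male-biased kidney genes differed by a median of -2.68 on the log2 scale from other proximal tubule markers, whose median was -1.19. This value decides nothing, since the genes were picked after their values were seen and sex goes with the obstruction. For the lung, bleomycin lung 3 had the female pattern, and its median difference from bleomycin lungs 1 and 2 over the genes called in UUO-mouse lungs was -0.07 in the direction of those calls, but 1 sample excludes nothing. Sex and kidney fibrosis cannot be told apart in either UUO comparison.

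The second pattern is the liver transcripts in healthy lung 3 and UUO-mouse lung 1. The 15 transcripts, a list written after the data were seen, were higher by a median of 7.28 and 4.98 on the log2 scale than in the other lungs of the group. In these 9 of the 15 were at background, so the medians are limits, at least 7.23 and 4.93 with the background limit in their place, and 15 and 13 transcripts stayed over 2 log2 units higher. The excesses had a correlation of 0.96 across genes between the 2 samples, which fits liver tissue or liver RNA in these 2 samples. A change of the whole mouse would show in its kidney too, but the kidney of the healthy mouse had an excess of -0.72. Liver genes such as Serpina10 in the difference between organs may therefore owe part of their size to healthy lung 3. Serpina10 kept its call without healthy lung 3, the only one of these 2 samples in that comparison. In the kidneys the list had medians of 7.05, 6.27 and 6.01 in the healthy and 4.87 and 4.80 in the UUO samples, so the fall of Mup2, a liver transcript too, is left open.

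The third pattern is Scgb1a1 in the UUO kidneys, at 22% and 10.1% of its healthy lung level. Lung RNA carried over in the proportions of whole lung would bring the other lung transcripts in like shares. The 6 compared (Sftpa1, Sftpb, Sftpc, Sftpd, Cxcl15 and Akap5) had medians of 0.43% and 0.15%, the highest being Sftpc at 3.36% and Sftpd at 1.54%. Such carry-over therefore does not explain Scgb1a1, as far as compressed signals at high intensity allow shares to be compared. Carry-over of RNA rich in club cells, which would bring Scgb1a1 in a larger share, was not tested. The smaller shares of Sftpc and Sftpd remain open. The test does not tell which kidney cells could make the transcript.

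The counts of genes called were set against the other splits of the same samples, as planned. With 3 against 3 samples there are 10 splits, so no share under 0.05 can be reached; in each comparison 1 split, the real one, reached its count. The highest other split called 0 genes for bleomycin against healthy lung (5019), 2 for UUO-mouse against healthy lung (1265), 0 for bleomycin against UUO-mouse lung (5828) and 0 for healthy kidney against lung (7762), where 4 splits divide all 3 mice. Each other split mixed samples of both groups, so any difference between the groups, whatever its cause, widened the spread. Low counts in these splits therefore decide nothing about the cause of the calls.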

How the results depend on the processing

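Of the alternatives, the joint omission of the 2 lungs with liver transcripts and the replicate block of the list tests were chosen after the data were seen. The counts of genes stayed within 1.5 times of the value reported in 13 of 14 alternatives for bleomycin lung (4855 to 6626), 14 of 17 for UUO-mouse lung (891 to 1846), 13 of 14 for UUO kidney (3646 to 5921), 15 of 16 for bleomycin against UUO-mouse lung (5686 to 7118), 13 of 14 for kidney against lung (7389 to 8547) and 13 of 13 for the difference (3763 to 6486). Similar totals need not hold the same genes. With the deposited matrix values, 3340 of 5019 calls in bleomycin lung and 3108 of 5238 in the difference recurred in the same direction. Median scaling kept 638 of 1265 in UUO-mouse lung. Without background correction 4690, 4854 and 1143 of these calls recurred in that order. A 2-fold threshold, which by construction calls fewer genes, left 2050, 260, 2553, 2586 and 4626 in the first 5 comparisons. For UUO-mouse lung, array quality weights gave 2924 (the cause was not tested) and leaving out the 2 lungs with liver transcripts 345, with fewer samples. Leaving out each sample gave 4107 to 4661 genes for bleomycin lung, 303 to 1272 for UUO-mouse lung, 3741 to 4819 for UUO kidney, 4948 to 5674 for bleomycin against UUO-mouse lung, 7140 to 7446 for kidney against lung and 4612 to 5199 for the difference, and 19 to 22, 3 to 8, 16 to 22, 16 to 18, 23 to 29 and 12 to 18 lists. Where this left 1 UUO kidney, it is assumed to vary like the other groups. With an estimated correlation the lists called were 0 for bleomycin lung, 0 for UUO-mouse lung, 0 for UUO kidney, 0 for bleomycin against UUO-mouse lung, 2 for kidney against lung and 0 for the difference; this correlation widens the test. With fry, which asks whether a list changed at all and not whether it changed more than other genes, they were 21 for bleomycin lung, 1 for UUO-mouse lung, 23 for bleomycin against UUO-mouse lung, 30 for UUO kidney, 41 for kidney against lung and 25 for the difference. The overlaps of calls stayed within 1.5 times without the filter and without background correction, but the counts for independent lists did not: without the filter, which adds genes at background, they were 664.5 for 1066 calls in the same direction in bleomycin lung and UUO kidney, and 153.3 for 321 in bleomycin and UUO-mouse lung. The excess over independent lists thus depends on the filter.

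Changes of named genes that turned sign did so under scalings that move all genes: Cldn5 in bleomycin lung to 0.09 and Ocln in the difference to 0.13 with the deposited matrix values, and, between bleomycin and UUO-mouse lung, Pecam1 to 0.66 and 0.63, where it passed, Tjp1 to 0.17 and 0.20 and Ocln to 0.19 and 0.34 under median scaling and with the matrix values. In UUO-mouse lung, 12 of the 23 named genes that passed kept their call under every alternative, against 40 of 49 in bleomycin lung, 48 of 55 in UUO kidney, 15 of 21 in bleomycin against UUO-mouse lung, 19 of 19 in kidney against lung and 28 of 33 in the difference. With the replicate number as a block, 4855, 940, 4718, 5745, 7703 and 5048 genes passed in the order above, and 19, 5, 19, 17, 26 and 14 lists. This block lost the B cell list in the difference (adjusted p 0.0548), Cldn5 in bleomycin lung (0.0514) and Mup2 in UUO kidney (0.0888), and it gained neutrophil markers in UUO-mouse lung, angiogenesis genes in UUO kidney, and matrix proteases and acute phase genes in kidney against lung. Replicate numbers do not pair the mice. The animal as a random block left 1 list in UUO-mouse lung, lost the acute phase list in bleomycin lung, the pan-endothelial list in UUO kidney and the natural killer and heart muscle lists in kidney against lung, and lost Mup2 in UUO kidney (0.0514). It gained angiogenesis genes in UUO kidney and in the difference, and alveolar type 2 markers in UUO kidney. Its gene counts were 5012, 1265, 5013, 5850, 7924 and 5356, and the paired fit of 3 mice gave 7536 for kidney against lung. Probes at background in a group give bounds only, and 32.4% to 41.5% of probes above background limit the lists to their brighter members.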

Other observations

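The tests in this part were all chosen only after the results were seen. Male-biased and female-biased kidney genes moved apart in the UUO kidney: Cyp2j13 (-4.78, adjusted p = 1.15e-07), Cyp4b1 (-4.70, adjusted p = 6.27e-08) and Cyp7b1 (-4.49, adjusted p = 0.00172) fell, while Cyp4a14 (4.38, adjusted p = 9.09e-07), Abcc3 (3.94, adjusted p = 4.64e-06) and Slc7a12 (2.34, adjusted p = 2.95e-05) rose on the log2 scale. Kap, the androgen-regulated kidney protein, fell by 2.71 on the log2 scale. These genes were chosen after their values were seen.

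Kidney transcripts were above background in 10 of 12 cases in bleomycin lung 1, in 4 in healthy lung 1, 2 in bleomycin lung 2, 1 in bleomycin lung 3 and 0 in the other lungs. In bleomycin lung 1 Spink1 stood at 9.51 and Umod at 9.07, or 3.62% and 2.4% of their kidney levels. The same sample had Xist at 5.52, above background, beside Eif2s3y at 9.66. Heart muscle genes had mean log2 levels of 9.52, 10.82 and 5.63 in healthy lungs 1, 2 and 3 and of 8.23, 5.999 and 7.70 in the UUO-mouse lungs, and skeletal muscle genes of 7.28, 10.95 and 5.49 and of 6.35, 5.43 and 6.09. Red blood cell genes stood between 6.66 and 6.87 in the bleomycin lungs and at 10.2, 9.97 and 10.3 in the healthy lungs. No explanation of these values was tested.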
